A study of Mus musculus with 9 samples.

How the data were processed

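Whole-testis total RNA of juvenile mice was hybridised to 2-colour spotted cDNA arrays, on which a knockout and a wild-type sample labelled with different dyes compete for the same spots. There were 9 arrays, each with the RNA of 1 Spo11 knockout and 1 wild-type testis sample: 4 with mice of 15 days and 5 with mice of 12 days. Per the labels, knockout RNA carried Cy3 on all 4 arrays at 15 days, whereas at 12 days it carried Cy5 on 3 arrays (replicates 1, 4 and 5) and Cy3 on 2 arrays (replicates 2 and 3). Replicates are numbered in order of deposit. The design text of the series describes different mouse pairs of a litter in quadruplicate, while 5 arrays are labelled as 12 days. Whether 2 of these shared RNA is not given in the sources used here, so each array counted as 1 replicate, and p-values could be too small if some shared RNA.

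The deposited values were log ratios, read here as log2. Per the design text, the authors scanned the arrays on a GenePix 4000A scanner, extracted and flagged spots with GenePix 3.0, centred each array on its median, and called genes with the SAM modified t statistic at a 1% false discovery rate and a 1.5-fold threshold. The log base, the background correction and the direction of the ratio are not given in the sources used here. Every column had a median of 0. Values had 2 decimals in 8 columns and 3 decimals in 1 column, that of 12-day replicate 5. No scanner intensities were used here, so signal over background is unknown, and the number of arrays limits the precision. Between 11628 and 14724 of 16128 probes had a value on an array.

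The platform annotation, which is old, gave exactly 1 gene for 9604 probes, several genes for 213 and none for 6311. Symbols were looked up by Entrez ID in a RefSeq gene table of assembly GRCm38.p6, which matched 98.9% of the probes with 1 gene and also gave the chromosome of each gene. The series names no genome build, so no coordinates are given. Probes of 1 gene were averaged on each array. Among 167 changed genes with more than 1 probe, 15 had probe means of both signs. A probe without exactly 1 gene was kept as a feature of its own and is called unlisted below. No probe was annotated to Spo11, so the targeted gene could not be used to check the labels.

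Arrays were centred again on their median, which moved nothing. Log2 ratios were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05). At 15 days the mean of the 4 arrays was tested against 0 for features with at least 3 values. At 12 days the model held a knockout coefficient and a dye intercept, for features with at least 4 values and both orientations. The difference between the ages came from 1 model of all 9 arrays with a shared dye term, which the 12-day arrays alone can estimate. As all arrays at 15 days had knockout in Cy3, this estimate equals the difference between their mean and that of 12-day replicates 2 and 3. The 3 arrays with knockout in Cy5 had a weight of 0 in it and entered the estimate of the spread only, so that 4 arrays were set against 2. Gene lists were fixed before the data were examined and tested with camera (preset correlation 0.01, at least 5 members), with an estimated correlation and fry beside it. X-linked genes were also compared with the other chromosomes by a two-sided Fisher's exact test.

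By the labels, a Cy5 over Cy3 ratio is knockout over wild type where knockout carried Cy5, and the opposite where it carried Cy3. This reading was fixed as the main one. Arrays of the same orientation from the 2 ages nevertheless correlated below 0, so the direction is unsettled. Values at 15 days are therefore given with their sign as deposited, values at 12 days as knockout over wild type under the Cy5 over Cy3 reading, and the age difference under both readings of the 15-day arrays.

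The genes named were chosen by a rule set before the data were examined. It took, among genes past the threshold with the same sign on every array, the 12 highest and 12 lowest, or the 5 of smallest p in a direction where fewer than 5 passed, and up to 4 members of smallest p from each list. For the age difference, the same sign on every array was taken to mean that the arrays of the 2 ages did not overlap, and the text names the 5 highest and 5 lowest of these genes.

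Alternatives set beforehand covered missing values, centring, scaling, quantile normalization, single probes, robust empirical Bayes, a stricter threshold, a SAM-type statistic written here, dye terms, the number range in the array titles, the direction of the ratios and each array left out in turn. Subtraction of the median of the 100 nearest spots on each side in probe order, and the turned 15-day sign, alone or with 1 array left out, were added after seeing the data. The tests were checked on simulated arrays with the real spread and 200 changed features. At a true log2 change of 1, limma recovered 82 of 100 features at 15 days, 82 of 100 at 12 days and 61 of 100 for the age difference. At a true change of 2 it recovered 93, 96 and 96 of 100. These simulations assumed independent features, 1 spread per feature on all arrays of a comparison, and no dye effect at 15 days. With fewer than 200 changed features the adjustment is stricter, so the shares recovered could be lower. In the real 12-day data Mnd1, at 1.48, did not pass (limma adjusted p = 0.59). Plots were drawn with matplotlib 3.10.9.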

Results

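Spo11 encodes the topoisomerase-like protein that makes the DNA double-strand breaks from which meiotic recombination starts. Testis RNA of juvenile Spo11 knockout and wild-type mice was compared on 2-colour cDNA arrays at 15 days (4 arrays) and at 12 days (5 arrays), 1 knockout against 1 wild-type sample per array. The share of probes with a value was 72.1% and 72.9% on 12-day replicates 1 and 2, and from 86.8% to 91.3% on the other 7 arrays. The log2 ratios of an array had an SD of 0.31 to 0.47 at 15 days and of 0.21 to 0.43 at 12 days. Values of spots that follow each other in probe order correlated, most on 12-day replicate 5 (r = 0.65) and 15-day replicate 3 (r = 0.48), and least on 12-day replicate 1 (r = 0.11).

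The direction of the ratios is not settled. The 4 arrays at 15 days resembled each other (r = 0.38 to 0.60 across probes, which are not independent replicates). All of them had knockout RNA in Cy3, as had 12-day replicates 2 and 3, yet they correlated below 0 with both, with r from -0.38 to -0.33 for replicate 3 and from -0.25 to -0.11 for replicate 2. If the 15-day values are Cy5 over Cy3, a value below 0 is a gene higher in the knockout. If they are knockout over wild type, it is a gene lower in the knockout. The 15-day values are thus described as above or below 0, and turning the sign turns every one of them. At 12 days, where arrays of both orientations exist, a value is knockout over wild type if the ratios are Cy5 over Cy3. As deposited, 12-day arrays of opposite orientation correlated at r = 0.0044 to 0.29 (mean 0.13). Those of the same orientation correlated at -0.13 to 0.45 (mean 0.15). A knockout effect in Cy5 over Cy3 ratios would pull opposite pairs below 0, while a gene's own dye effect would raise both kinds. The direction at 12 days is therefore not settled by these values either.

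The 15-day comparison asks which transcripts change in the testis without Spo11. Among genes with the same sign on all 4 arrays, the lowest ratio was that of Cfap206, which encodes a cilia and flagella protein, at -2.87 (SE 0.23, 7.31-fold), followed by the glucose transporter gene Slc2a3 at -2.16 (SE 0.23, 4.46-fold). Cfap52 lay at -1.76, the radial spoke gene Rsph1 at -1.73, the dynein regulatory complex gene Ccdc65 at -1.80 and the centrin gene Cetn4 at -1.61. Also among the 12 lowest were Ndufaf3 (-2.11), an assembly factor of respiratory complex I, Armt1 (-1.69), Asrgl1 (-1.64), Phf7 (-1.64), Mif4gd (-1.60) and Lyar (-1.56). The highest ratio among such genes was that of Mnd1, at 2.42 (SE 0.21, 5.36-fold), whose product acts with that of Psmc3ip in meiotic strand exchange. It was followed by Olfr75-ps1 (1.56), Adgre4 (1.39), Pde4dip (1.37), Etv5 (1.20), Fbxw17 (1.12), Aurkb (1.09), Mrps25 (1.08), Zfp708 (1.03), Setd5 (1.02), Spryd7 (0.99) and Gas2l1 (0.96). Each of these 24 genes had the same sign on all 4 arrays, with limma adjusted p from 0.00058 to 0.031. On replicate 4, however, Mrps25 (0.06), Spryd7 (0.07), Aurkb (0.09), Pde4dip (0.14) and Gas2l1 (0.14) hardly moved. Adgre4 (1.28, 2.85, 1.13 and 0.28 on replicates 1 to 4) and Pde4dip (1.29, 2.89, 1.15 and 0.14) had similar values, so they need not be separate changes. At 12 days, under the Cy5 over Cy3 reading, the signs of Slc2a3, Armt1, Phf7, Fbxw17 and Zfp708 followed the knockout's dye on every array. Zfp708 lay at -2.02, -1.2 and -0.288 with knockout in Cy5, and at 1.17 and 0.64 with knockout in Cy3. A gene's own dye effect gives such a pattern, so the 15-day ratios of these genes may partly be dye effects.

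**Figure D1:**
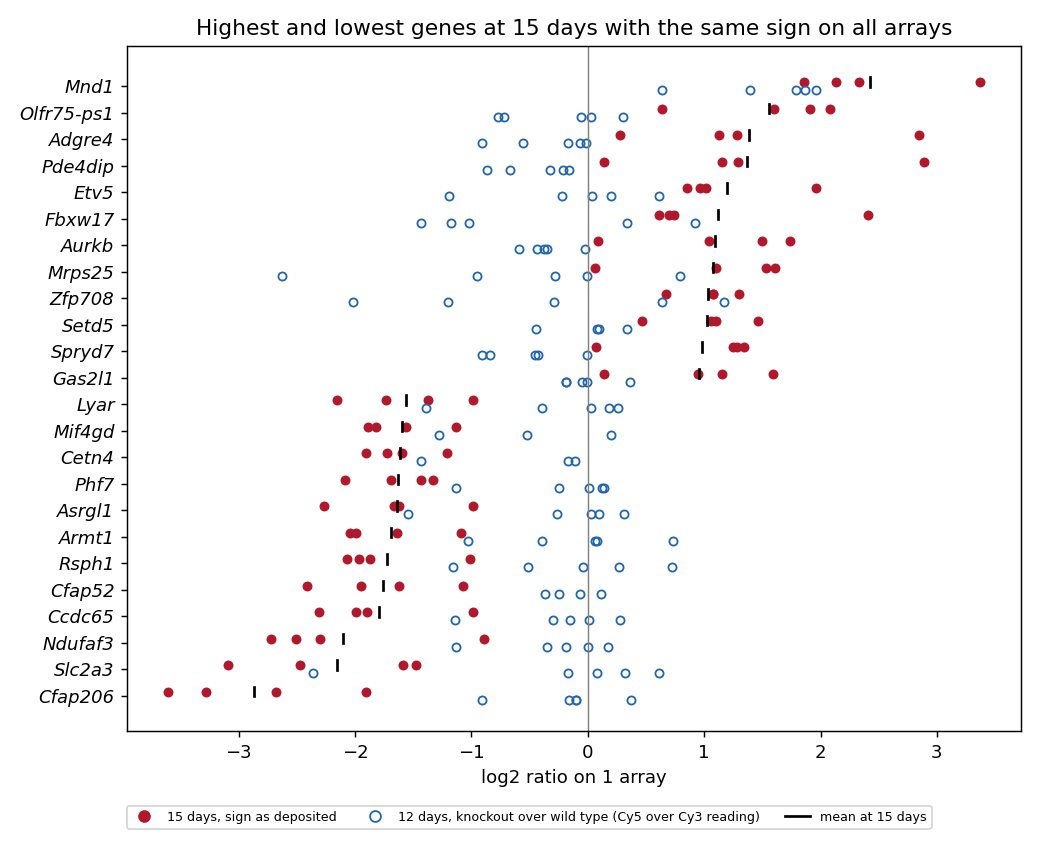
Log2 ratios (horizontal axis) of the 12 highest and 12 lowest genes that passed at 15 days with the same sign on all 4 arrays, 1 row per gene. Filled points are the 4 arrays at 15 days with the sign as deposited, black ticks their mean, and open points the 5 arrays at 12 days as knockout over wild type under the Cy5 over Cy3 reading. Mnd1 lies above 0 on all 9 arrays, from 0.64 to 3.37.

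Of 12198 features tested at 15 days, 1515 passed, 860 above 0 and 655 below 0. Among the 6958 genes tested the balance was the other way, with 281 above 0 and 501 below 0, and 12 genes above and 42 below 0 by at least 2-fold. Unlisted features made up 67.3% of those above 0, against 43.0% of all features tested. All 4 arrays had 1 dye orientation, so a gene's own dye effect enters these values. The dye coefficient estimated from the 12-day arrays correlated with the 15-day arrays at r = -0.34 to -0.17. A joint fit of both ages, over 9851 features, passed 882 features at 15 days without a dye term, 763 with it under the label reading and 17 with it and the 15-day sign turned. The count fell to 711, 586 and 357 without replicates 1, 2 and 3, and 242 features passed at an adjusted p under 0.01 with a 1.5-fold change.

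Markers of pachytene spermatocytes, the germ cells in mid meiotic prophase, lay below 0 at 15 days, 7 of 11 past the threshold and none above it, with a list median of -0.55. Adjusted over the list alone, 8 were below 0. Besides Slc2a3, Rsph1 and Lyar these included Ccnb1ip1 (-0.58, SE 0.11), a crossover factor. Of 13 genes of the piRNA pathway, which silences transposons in germ cells, 5 were below 0 and none above, also when adjusted over the list alone. The RNA helicase gene Ddx4 lay at -1.17 (SE 0.11), Gtsf1 at -0.85, Tdrd9 at -0.79 and Tdrd1 at -0.66. Of 12 spermatogonial genes 3 were above 0 and none below, the same numbers over the list alone: Etv5, a transcription factor of spermatogonial stem cells, Ccnd1 (0.42) and Uchl1 (0.36). Camera gave adjusted p = 1.4e-05, 0.00013 and 0.010 for the 3 lists with the preset correlation. With an estimated correlation adjusted p = 0.36 for each of them, and fry, which tests whether the genes of a list move on balance in 1 direction, gave adjusted p = 0.028 for each. The spermatogonial list no longer passed camera without replicate 2 (adjusted p = 0.058) or in the joint fit with a dye term under the label reading (0.26), and the piRNA list in that fit with the 15-day sign turned (0.056).

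Genes of meiotic recombination and synapsis moved both ways at 15 days, 3 of 25 above 0 and 4 below, with the same numbers adjusted over the list alone. Psmc3ip lay at -1.25 (SE 0.11), opposite to its partner Mnd1, Brca2 at -0.74 and Mei1, which is needed for break formation, at 0.73. Of 15 general germ cell genes 2 were above 0 and 4 below (3 and 4 adjusted over the list alone), among them Taf7l at 0.78 and Hsp90aa1 at -0.82. Those below also included Ddx4, Gtsf1 and Tdrd1, already counted in the piRNA list, so the lists are not independent. Another list also held 5 of the 15 general germ cell, 6 of the 13 piRNA and 5 of the 11 pachytene genes. Of 38 cell cycle genes 3 were above 0 and 7 below (4 and 9 adjusted over the list alone). Cyclin B2 (Ccnb2) lay at -0.995, Bub1b at -0.61 and Cks2 at -0.75, against Aurkb above 0. Of 17 genes of apoptosis and the p53 response, Diablo (-0.82) and Birc5 (-0.40) were below 0 and Btg2 (0.39) above, and the same numbers passed over the list alone. Camera passed none of these 4 lists, with adjusted p from 0.12 to 0.90.

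Ribosomal protein genes lay slightly below 0 at 15 days, 9 of 73 past the threshold and none above, or 11 adjusted over the list alone. Of all 6958 genes tested 501 passed below 0. The list median was -0.22, with a camera adjusted p = 1.8e-07, and adjusted p = 0.48 with an estimated correlation and 0.073 by fry. Rpl39l, a paralog of Rpl39 expressed in testis, was the member of smallest p at -0.88 (SE 0.14), followed by Rpl24 (-0.46), Rpl9 (-0.44) and Rpl36 (-0.52).

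Of all 6958 genes tested at 15 days 782 passed, and each list of somatic cell markers held from 0 to 2 passing genes. These lists are too small to show whether somatic markers passed less often than other genes. None of 16 Sertoli cell genes passed, over all features or adjusted over the list alone. Of 13 Leydig cell genes Nr5a1 passed at 0.43, and none adjusted over the list alone. Of 18 peritubular and fibroblast genes, Lum (-0.57) and Col1a1 (0.41) passed in opposite directions. Of 7 macrophage genes Lyz2 passed at -0.61, and of 9 endothelial and blood genes Cdh5 at 0.78. The numbers over the list alone were the same for these 3 lists. Camera passed none of the 5 somatic lists, with adjusted p from 0.18 to 0.90, while fry passed the endothelial and blood list alone (adjusted p = 0.044). Only 4 spermatid genes were measured, too few for a list test, and of these Txndc2 passed at 0.81, while 2 passed above 0 adjusted over the list alone.

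**Figure D2:**
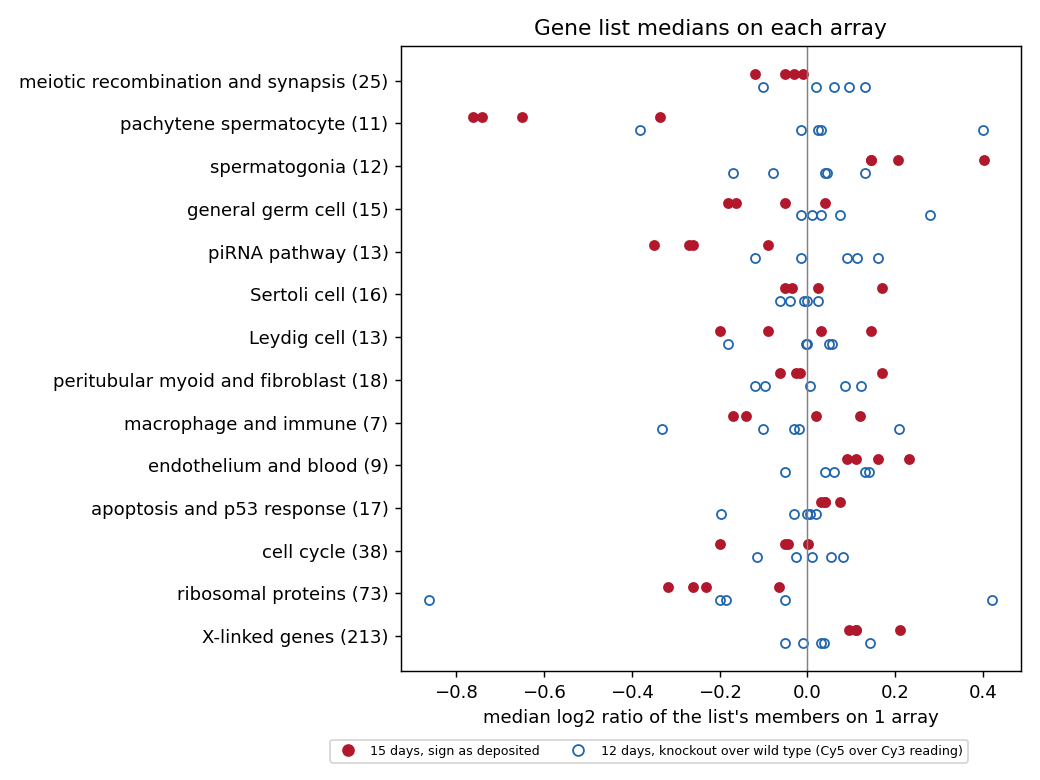
Median log2 ratio (horizontal axis) of each gene list on each array, with the number of measured members in parentheses. Filled points are the 4 arrays at 15 days with the sign as deposited, and open points the 5 arrays at 12 days as knockout over wild type under the Cy5 over Cy3 reading. Pachytene medians lie from -0.76 to -0.34 at 15 days and from -0.38 to 0.40 at 12 days.

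X-linked genes moved opposite to the pachytene markers at 15 days. Of 207 tested, 29 passed above 0 and 1 below, or 36 and 3 adjusted over the list alone, and the median was 0.15. The members of smallest p were Huwe1, a ubiquitin ligase gene, at 0.84 (SE 0.11), Ezhip at 0.77, Taf7l, a germ cell subunit of the general transcription machinery, at 0.78 and Cfap47 at 0.81. On the other chromosomes 246 of 6662 genes passed above 0, so that the share was 14.0% on the X against 3.69% elsewhere (odds ratio 4.25, 95% interval 2.71 to 6.47, Fisher's exact p = 2.5e-09). Below 0 it was 0.483% against 7.46% (Fisher's exact p = 4e-06). Fisher's test treats genes as independent, which they are not. Camera gave adjusted p = 8.5e-05, and adjusted p = 0.36 with an estimated correlation and 0.028 by fry. The only Y-linked gene tested passed above 0.

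**Figure D3:**
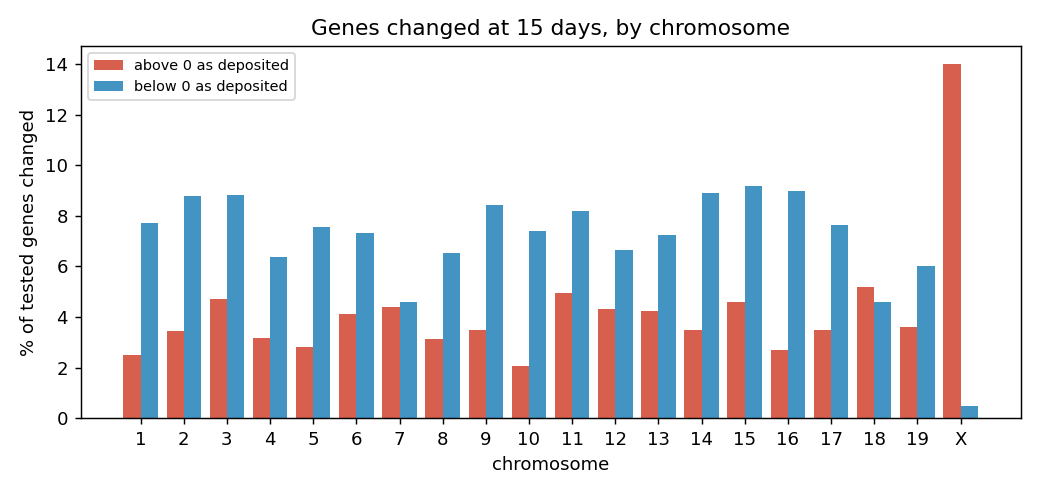
Share of tested genes that passed at 15 days (vertical axis, percent) on each autosome and the X chromosome, above 0 and below 0 as deposited. The X stands at 14.0% above 0, and no autosome exceeds 5.17%.

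The 12-day comparison asks for changes at a younger age, with fewer late spermatocytes in the testis, and no feature passed. Mnd1 had the smallest p, at 1.48 (SE 0.18, 2.78-fold), and was above 0 on all 5 arrays whichever dye the knockout carried, but with a limma adjusted p = 0.59. The other genes of smallest p with 1 sign on every array were Gm3636 (0.42), Emc7 (0.44), Kctd12 (0.31) and Ofd1 (0.27) above 0, and Prnp (-0.61), Gprasp2 (-0.55), Snord123 (-0.41), Srp19 (-0.51) and Phtf1 (-0.44) below it, each with adjusted p = 1.0. Of 10075 features limma passed 0, with 269 at an unadjusted p under 0.05 where chance gives 504, and the SAM-type test passed 12. The limma count at an unadjusted p under 0.05 was 910 without turning by the dyes or a dye term, and 607 without replicate 5. No feature passed after adjustment in either. If the ratios are Cy5 over Cy3, the fit without turning tests mostly a gene's own dye effect, so its count does not measure knockout effects. With the range of array title numbers, a possible batch, as a block, limma also passed 0.

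No member of any list passed at 12 days over all features. Adjusted over the list alone, 1 meiotic recombination gene (Mnd1) passed above 0 and 1 endothelial and blood gene (Hba-x, -0.36) below. Slc2a3 lay at -0.46 (SE 0.30), Lyar at -0.32 and Rsph1 at -0.22, and the median of 7 pachytene markers was -0.22. The direction of these values depended on replicate 3: without it the 3 genes lay at 0.08, 0.07 and 0.06, the median was 0.07 over the 6 markers left, and camera gave the list as up (adjusted p = 0.37). The median was also -0.05 without replicate 1, -0.36 without replicate 5 and -0.50 without replicate 2, where camera gave the list as down (2.8e-05). X-linked genes had a median of 0.04 and a camera adjusted p = 0.0029, ribosomal protein genes a median of -0.16 and adjusted p = 3e-07. With an estimated correlation adjusted p = 0.95 for both, and by fry 0.81. Each call rested on single arrays: the X-linked list had a camera adjusted p = 0.49 without replicate 3 and 0.050 without replicate 5, with medians of 0.02 and 0.03, and the ribosomal list 0.82 without replicate 1. The ribosomal median was -0.0054 without replicate 1 and -0.32 without replicate 5, and ranged from -0.86 on replicate 1 to 0.42 on replicate 5. Camera passed no other list, with adjusted p from 0.24 to 0.99.

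Whether the effect differed between the ages depended on the reading, and the estimate sets the 4 arrays at 15 days against 12-day replicates 2 and 3 only. Under the label reading, 231 of 9851 features differed, 129 with a higher knockout over wild-type ratio at 15 days and 102 with a lower one. Among passing genes whose arrays of the 2 ages did not overlap, the highest differences were Slc2a3 (3.42, SE 0.56), Cfap206 (3.14), Ndufaf3 (2.77), Armt1 (2.40) and Asrgl1 (2.36), and the lowest Mnd1 (-3.64, SE 0.41), Huwe1 (-1.45), D6Ertd474e (-1.32), Lrrc47 (-1.02) and Pdk1 (-0.98). With the 15-day sign turned limma passed 0 features, with 650 at an unadjusted p under 0.05, and Mnd1 was higher at 15 days by 1.21 and Cfap206 lower (-2.60), neither past the threshold. The label-reading count ranged from 10 without 15-day replicate 3 to 465 without 12-day replicate 5, and was 59 and 50 without 12-day replicates 2 and 3. Without replicate 3 Slc2a3 fell short of the threshold at 2.33 (adjusted p = 0.079), Cfap206 at 2.50 (0.066), Ndufaf3 at 2.30 (0.11) and Asrgl1 at 1.54 (0.12). Huwe1 did without replicate 2, at -1.36 (0.068), and D6Ertd474e, Lrrc47 and Pdk1 did without either array. Of these 10 genes Mnd1 and Armt1 alone passed without each of the 2, at -3.06 (0.028) and 2.08 (0.0498) without replicate 3.

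As groups, pachytene, piRNA and X-linked genes differed between the ages under both readings by camera with the preset correlation. With an estimated correlation none of them passed, with adjusted p = 0.36, 0.36 and 0.11 under the label reading and 0.32 for each with the sign turned. The median difference was 1.82 for 7 pachytene markers under the label reading (adjusted p = 0.00011) and -0.63 with the sign turned (0.0034). Without 12-day replicate 3 these medians were 1.29 and -1.41 over 6 markers, and without replicate 2 they were 2.44 and -0.07. The median difference of 11 piRNA genes was 0.31 (0.031) and -0.19 (0.029). Their label-reading call was lost without 15-day replicate 4 (0.055) or 12-day replicate 3 (0.089, median 0.15), and that with the sign turned without 15-day replicate 4 (0.071) or 12-day replicate 1 (0.051). The medians were -0.22 (5.2e-07) and 0.06 (0.0072) for 188 X-linked genes, the latter 0.0038 without 12-day replicate 2 and 0.10 without replicate 3. Ribosomal protein genes passed under the label reading alone (adjusted p = 4.7e-05, or 0.90 with an estimated correlation) and spermatogonial genes with the sign turned alone (0.0046, or 0.32). With the sign turned no list passed without 12-day replicate 2, the adjusted p being 0.60 for pachytene, 0.11 for piRNA and spermatogonial and 0.61 for X-linked genes. By fry the pachytene (0.027), piRNA (0.018) and X-linked (0.013) lists passed under the label reading and none with the sign turned, the smallest being adjusted p = 0.17. Across the 9851 features, which are not independent replicates, the effects at the 2 ages correlated at r = -0.23 (Spearman's rho -0.25) under the label reading and at 0.23 (0.25) with the sign turned.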

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

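The tests of the first 2 paragraphs below were chosen after the patterns were seen, as were those of unlisted features, while the counts over other splits of the arrays were planned. The 15-day arrays correlated below 0 with 12-day arrays of the same dye orientation. Either the 15-day ratios were deposited as knockout over wild type (Cy3 over Cy5), or the knockout effect turned round between the ages. The 12-day dye coefficient correlated with the 15-day values at a mean r of -0.26, and at -0.19 without 12-day replicate 3, as the first explanation requires. The 12-day arrays with knockout in Cy3 followed the 15-day values far more (slopes 0.26 and 0.34) than those with knockout in Cy5 (-0.24 to 0.01), and such unequal effects also enter the dye coefficient. The 2 explanations therefore cannot be told apart. With all ratios Cy5 over Cy3, a dye effect shared by both ages would push arrays of the same orientation above 0. The 8 such pairs correlated at r = -0.38 to -0.11. Such a dye effect could thus add to the pattern only if the 15-day ratios are Cy3 over Cy5.

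Genes below 0 at 15 days moved on 12-day replicate 3. The median of these 501 genes was -0.29 there and from -0.07 to 0.12 on the other 4 arrays. Swapped dyes would put Mnd1 below 0 on that array, but it lay at 1.79, between 0.64 and 1.96 on the others, which is evidence from 1 gene. A position effect of the kind that the local median removes is argued against by a median of -0.27 after its subtraction. The subtraction was incomplete, as spots that follow each other still correlated on this array (r = 0.079, against 0.12 before). A pair further into meiosis stays open as a candidate explanation only if the 15-day values are knockout over wild type, since under the label reading the knockout effect at 15 days is opposite to that on this array. The 183 X-linked genes that did not pass at 15 days had a median of 0.13 on this array, above the -0.05 to 0.01 of the others, but no stage was recorded for any mouse.

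Unlisted features made up most of those above 0 at 15 days, 579 of 860. An additive trend along the array is argued against as the whole cause, since 564 unlisted features were above 0 after subtraction of the local median. Spots that follow each other still correlated at r = 0.13 to 0.27 on the 15-day arrays after it, so part of such a trend may remain. Dim spots may contribute: 22.2% of the 12-day values of these features were missing, against 16.8% for unlisted features that did not pass and 9.31% for probes of named genes. Missing values stand for dimness only indirectly, and no biological explanation was tested.

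At 15 days the real assignment of knockout and wild type gave 1515 features and the highest other assignment 0, with 1 of 8 as large. At 12 days the real one gave 0 and the highest other 14, so that 15 of 15 were as large, which a real count of 0 makes certain. Both designs have too few assignments for a share under 0.05. For the age difference under the label reading, 1 of 100 splits of the 9 arrays, the real one, reached its 231 features, with 22 at most elsewhere. Many of the other splits mix dye orientations, so they weight the arrays otherwise than the real split. The real split thus stood apart from those drawn, but this excludes neither chance nor a dye effect nor a wrong sign. With the 15-day sign turned the real split gave 0, so that all 100 splits were as large by construction and the comparison says nothing about chance. The highest there, 28, set 12-day replicate 3 with the 15-day arrays, which points to a structure of the arrays.

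Under the label reading 231 features differed between the ages, in an estimate to which 12-day replicates 2 and 3 alone contribute at that age. The highest and lowest differences among genes whose arrays of the 2 ages did not overlap were Slc2a3 (3.42), Cfap206 (3.14), Ndufaf3 (2.77), Armt1 (2.40), Asrgl1 (2.36), Mnd1 (-3.64), Huwe1 (-1.45), D6Ertd474e (-1.32), Lrrc47 (-1.02) and Pdk1 (-0.98). By camera with the preset correlation the pachytene, piRNA and X-linked lists differed under both readings but in opposite directions, with medians of 1.82, 0.31 and -0.22 under the label reading (1.29, 0.15 and -0.19 without 12-day replicate 3) and -0.63, -0.19 and 0.06 with the sign turned. With an estimated correlation none of the 3 passed, with adjusted p = 0.36, 0.36 and 0.11 under the label reading and 0.32 for each with the sign turned. Without 12-day replicate 2 none passed with the sign turned, the pachytene median then being -0.07 and the X-linked one 0.0038, against -1.41 and 0.10 without replicate 3.

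An array stood far from the others of its age in 12 of 164 sets of values, and chance gives about 1 in 20. At 15 days these were the X-linked median on replicate 2 (0.21, others 0.10 to 0.11), Etv5 (1.96), Fbxw17 (2.41) and Mei1 (1.07) on replicate 3, Gtsf1 on replicate 2 (-1.07) and Spryd7 on replicate 4 (0.07, others 1.25 to 1.34). At 12 days these were Slc2a3 on replicate 3 (-2.36, others -0.17 to 0.61), the Leydig cell median on replicate 1 (-0.18), Akr1c14 (1.24) and Rpl12 (-1.34) on replicate 2, and Casp9 (-1.10) and the apoptosis median (-0.20) on replicate 5.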

How the results depend on the processing

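No paired analysis was possible because replicate numbers follow the order of deposit and the arrays of the 2 ages came from different mice, while each array already sets a knockout against a wild-type sample. The p-values measure the spread between mouse pairs. All alternatives set beforehand were run. Leaving out 12-day replicate 2 or 3 left 1 array of that orientation, assumed to vary like the others.

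At 15 days 1515 features passed, and 711, 586, 357 and 1021 without replicates 1 to 4 in turn, a range of 357 to 1021. The count was 242 at an adjusted p under 0.01 with 1.5-fold, 522 by the SAM-type test, 882 in a joint fit of both ages without a dye term, 763 with it, and 17 with it and the 15-day sign turned. Zfp708 then lay at -0.0047. The share of passing features below 0, 43.2%, became 52.1% with the local median subtracted. Among the values of the genes that the rule names, over all settings, 129 at 15 days and 157 for the age difference kept their direction but no longer passed. The direction was reversed in 1 value at 15 days and 99 for the age difference. Of the 99, 47 came without turning by the dyes, 26 with the 15-day sign turned and 26 with that and the local median subtracted. The cause of these shifts was not tested. At 12 days 0 passed whichever array was left out, 2 from the arrays of higher title numbers alone and 12 by the SAM-type test.

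The age difference of 231 features became 535 with arrays scaled, 744 after quantile normalization, 4 at the stricter threshold, 8.6e+02 (rounded to 2 digits) without turning by the dyes, 499 after subtraction of the local median, and 0 with the 15-day sign turned, with or without that subtraction. Leaving out 1 array gave 10 to 465: 23, 35 and 10 without 15-day replicates 1, 2 and 3, and 59, 50, 67 and 465 without 12-day replicates 2, 3, 4 and 5. Without turning by the dyes, with the 15-day sign turned, and with that and the local median subtracted, the difference was -2.87, -0.89 and -1.03 for Slc2a3, -2.91, -2.60 and -2.63 for Cfap206, -2.33, -1.45 and -1.45 for Ndufaf3, -2.15, -0.98 and -1.18 for Armt1, -1.94, -0.91 and -0.95 for Asrgl1, 1.86, 1.21 and 1.22 for Mnd1, 1.24, 0.24 and 0.34 for Huwe1, 0.98, 0.15 and 0.091 for D6Ertd474e, and 0.72, 0.31 and 0.083 for Pdk1. Lrrc47 was reversed in the first alone (0.84). The correlation between the ages, -0.23, was 0.23 with the sign turned, -0.13 without a dye term, and -0.26 to -0.14 with 1 array left out.

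Lists passing camera fell from 5 at 15 days, 2 at 12 days and 4 for the difference to 0 each with an estimated correlation. With the 15-day sign turned 4 passed for the difference, 0 with that and an estimated correlation, and 0 to 5 with that and 1 array left out (0 without 12-day replicate 2), the last chosen after seeing the data. With 1 array left out and no sign turned the 3 counts were 4 to 5, 1 to 4 (4 without replicate 2, 1 without replicate 3 or 5) and 3 to 4. The mean r of 12-day arrays of opposite orientation, 0.13, ranged from 0.068 without replicate 2 to 0.20 without replicate 3. Signal over background is unknown, so its limit on these results could not be measured.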

Other observations

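The axonemal group was named and its test chosen after the 15-day values were seen, while the test of genes near Spo11 was set beforehand. Genes of cilia and flagella stood out at 15 days beyond those named in the report. Of 29 tested genes with symbols of axonemal, intraflagellar transport or Bardet-Biedl families, 15 lay below 0 past the threshold, 51.7% against 7.01% of the other genes (Fisher's exact p = 1.8e-10). They included the radial spoke genes Rsph3a (-1.56) and Rsph9 (-0.72), the transition zone gene B9d1 (-1.42), Drc1 (-1.01), and the transport genes Ift122 (-0.78), Ift74 (-0.50) and Ift46 (-0.48). Above 0 were Cfap47 (0.81), an X-linked gene, and Bbs1 (0.44). Without the genes already among the 24 highest and lowest of the report it was 12 of 26 (Fisher's exact p = 5.1e-08). These data may thus hold a shift of the axonemal genes as a group, whose direction in the knockout has the same open sign as the other 15-day values.

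Genes near a targeted locus can carry variants of the strain in which it was made, so the 20 measured genes on each side of Spo11 on chromosome 2 were counted. Of these 40 genes 5 passed at 15 days, 12.5% against 11.2% elsewhere (one-sided Fisher's exact p = 0.47). The odds ratio of 1.13 had a wide interval, 0.34 to 2.91, so that an excess of a few genes could have been missed.

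There were 6 unlisted probes that followed Mnd1 across all 9 arrays at r above 0.9 and averaged above 1 at 15 days. Their r lay between 0.91 and 0.97 and their 15-day means between 1.05 and 1.90.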
